A study of Rattus norvegicus with 72 samples.

How the data were processed

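Total RNA from freeze-clamped rat liver was, per the labels, extracted with Trizol and RNeasy columns, checked for integrity on a Bioanalyzer and turned into labelled cRNA for Affymetrix Rat Gene 1.0 ST arrays. The 72 arrays come from 36 rats on 3 diets in 3 cohorts, with a control array from the liver removed at partial hepatectomy (PHx) and a second array from the remnant 1, 6 or 24 h later. The composition and length of the diets and the hour of surgery are not given in the sources used here. A 12 h time named in the series text was not analysed here. The titles and diet labels were used for the groups. The source names give the high fat and carbohydrate names the other way round, so that, if those are right, every EtOH minus CHO comparison is one of EtOH minus HF and the reverse, and every HF minus CHO difference has the opposite sign. Which labels are right was not tested. Scd, Slc2a5 and Pklr, genes that dietary carbohydrate induces, were lower in the livers titled HF than in those titled CHO (log2 -3.81, -1.51 and -1.10). EtOH 24 h replicate 4 carries a high fat diet tag on its PHx array, while its title and animal belong to ethanol. That array is marked as an outlier and did not enter the comparisons.

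Per the submitters' processing notes, the values were made with RMA in Affymetrix Expression Console, whose versions are not given there. All deposited values are on the log2 scale. The value table holds 72 arrays. The batch-corrected table holds the same 72 arrays after, per the file headers, RMA and a mixed-effects ANOVA correction by the authors with diet and time as fixed and batch and animal as random effects. It was checked that the batch-corrected values equal the value table plus a single constant per probe set and scan day, to within 0.00015, with a mean absolute shift of 0.115 to 0.219 per scan day. The authors' table without outliers holds 63 arrays, with array medians of 4.51 to 4.74. Its within-animal log2 differences depart from those of the value table by a median of 0.0189 and by at most 0.393. Of its 63 columns, 61 correlated best with the array of the same name. The CHO 1 h replicate 3 and CHO 6 h replicate 1 control columns correlated best with the PHx arrays of the same animals (r across probe sets, which are not independent replicates, after removal of each probe set's mean, 0.985 and 0.992, against 0.276 and -0.365 with their own names) and were left out.

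Of 29214 probe sets, 15310 map to 1 gene symbol, 323 to several and 13581 are not listed in the annotation. The probe set with the highest mean stood for each of 14506 genes (527 had more than 1), with no filter on dim genes. The tables used hold no detection calls, so a level under the array medians is not shown to lie above background. The fitted size of a change from or to such a level is therefore uncertain. The responses to PHx and their differences between diets were fitted in limma 3.58.1 (R 4.3.3, data.table version 1.17.8, statmod 1.5.0) on the 54 arrays of 27 animals with both arrays kept, with the animal as fixed block and 18 residual degrees of freedom. The controls were compared in limma on 29 arrays with the scan day as fixed block and 19 residual degrees of freedom. Each of the 8 scan days held animals of 1 cohort, so each response is measured within animals, and no test compares responses between times, which come from different animals. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, and for gene lists also adjusted over the list alone. There were 24 such comparisons. Each of 35 gene lists (cell cycle and growth, signalling and stress, metabolism, and markers of liver zones and of other cell types) was tested with camera at a preset correlation of 0.01, with p adjusted over the lists, and again with an estimated correlation. The mean, the median and the camera direction of a list differed in sign in 117 of 840 pairs of list and comparison, of which 0 were called. Response strength was compared with exact 2-sided permutation tests. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

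The groups, lists, rules for naming genes, tests of the comparisons and alternatives were chosen before the data were examined, except for the misplaced columns kept as named and several tests of explanations, which were chosen after. In the responses in the mean of the diets, in the differences between EtOH and each control diet and in the baseline comparisons, the genes that could be named were the 6 with the largest rise and the 6 with the largest fall among those called (changed the same way in every pair, for responses), the 4 with the smallest p of each list, and a fixed set of genes that includes Fos, Myc, Ccnd1, A2m, Igfbp1 and Cyp2e1. The text names those whose function or list it describes. Mki67, also in that set, has no singly annotated probe set.

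The pairing rests on the animal labels. After the group means were removed, the arrays of an animal correlated at a median of 0.15 across genes (over 0.1 in 15 of 27 pairs, lowest -0.766, highest 0.428), against -0.0145 with other animals. By time, 9 of 10 pairs at 1 h, 6 of 9 at 6 h and 0 of 8 at 24 h lay over 0.1 (highest 0.0852 at 24 h), so at 24 h the values do not bear out the pairing, which rests there on the labels alone. In groups of 2 animals the deviations mirror each other, so both pairs give the same value (0.382 for HF at 6 h and -0.246 for CHO at 24 h). The lowest value came from CHO 6 h replicate 4, the only animal of its scan day. The pipeline was tested on simulated data with the same animals. Changes of log2 0.5, 1 and 2 were recovered in 95.5, 98.5 and 100% of genes for the mean response at 24 h (4.4% false calls), in 29.9, 85.1 and 100% for EtOH minus CHO at 6 h (3.4% false) and in 9, 74.6 and 98.5% at 24 h (4.7% false). A baseline difference of log2 0.5 was recovered in 88% of genes. camera called the shifted list and 0 others. The simulated noise was independent between genes, while list members in the data are correlated (estimated at 0.536 for ribosome biogenesis in the response fit). The simulation therefore does not test how often camera at the preset correlation calls a correlated list falsely. Alternatives covered the block, the scan days and cohorts, the outlier arrays, the source table, dim genes (under the 25th percentile), probe set choice, array weights, the variance prior, renormalization and each animal left out in turn. The reading of the diets from the source names was not refitted, since it only renames the comparisons.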

Results

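Gene expression was measured in rat liver on 72 Affymetrix Rat Gene 1.0 ST arrays from 36 animals fed 1 of 3 diets, namely ethanol (EtOH), a high fat control (HF) or a pair-fed carbohydrate control (CHO). Each animal gave 2 arrays. The control array came from liver removed at partial hepatectomy (PHx), the surgical removal of part of the liver that sets off regrowth of the remnant, and the other array came from the remnant of the same animal 1, 6 or 24 h later. Every combination of diet and time held 4 animals. The submitters marked 9 arrays, from 9 animals, as outliers. The comparisons rest on the 27 animals with both arrays kept, in numbers of 4, 4 and 3 EtOH, 3, 2 and 3 HF, and 3, 3 and 2 CHO animals at 1, 6 and 24 h. The diets before surgery were compared on 29 control arrays (12 EtOH, 9 HF and 8 CHO), with 2 further CHO control columns left out because they carry the PHx values of the same animals. The labels are at odds on which control diet is which, and the diet names used here are those of the sample titles and diet labels. Scd, the stearoyl-CoA desaturase that dietary carbohydrate induces, stood at 5.52 in the control livers titled HF and 9.36 in those titled CHO. The values were deposited on a log2 scale, with array medians between 4.51 and 4.74. The number of animals limits the precision of every comparison. No sham-operated animals are listed, so a response here is the whole change from the liver taken at surgery to the remnant, passage of the hours included.

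The control livers show how ethanol-fed rats differed from the control diets before any surgery. Bmal1 (probe set 10710028), the transcriptional activator of the positive arm of the circadian clock, stood at a mean level of 6.71 in EtOH against 3.57 in CHO livers (log2 difference 3.13 ± 0.10 SE, adjusted p = 1.91e-17), the latter under the array medians, and its log2 difference from HF was 3.18. Dbp, an output gene that BMAL1 activates, was lower in EtOH livers, at log2 -3.60 ± 0.15 against CHO and -3.50 against HF. Ethanol-fed livers also held more mRNA of the phenobarbital-inducible cytochromes Cyp2b1 and Cyp2b2 and of the cell cycle inhibitor Cdkn1a. Against CHO, 13 of 20 cholesterol synthesis genes and 7 of 21 macrophage markers were higher, sets whose calls were lost with an estimated correlation (adjusted p = 0.251 and 0.393). They held less mRNA of Cyp7a1, the rate-limiting enzyme of bile acid synthesis.

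Against CHO, 1719 of 14506 genes differed in limma (925 higher and 794 lower in EtOH). Of 17 clock genes, 4 were higher and 10 lower (5 and 10 adjusted over the list alone), with a list mean of -0.67. Per3 and Per1, of the negative arm, were lower (log2 -2.52 and -1.30). Usp2, a deubiquitinase under clock control, was lower as well (-1.90). The clock list was the only list against CHO whose call held with an estimated correlation (camera adjusted p = 2.03e-06, and adjusted p = 0.0323 with an estimated correlation). Cholesterol synthesis had 13 of 20 members higher and 0 lower (19 higher adjusted over the list alone, camera adjusted p = 3.44e-13, and adjusted p = 0.251 with an estimated correlation). Its members Tm7sf2, Dhcr7 and Pmvk were higher by log2 1.64, 1.63 and 1.45. Among the targets of PPARa, the nuclear receptor that drives fatty acid oxidation, 11 of 33 were higher and 2 lower (14 and 3 adjusted over the list alone, camera adjusted p = 0.000271, and adjusted p = 0.393 with an estimated correlation). Cd36 was higher (1.68), and so was Pdk4 (2.38), while Ppara itself was lower (-1.15). Gpam, which starts triglyceride synthesis, was higher by log2 1.48 ± 0.15.

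Markers of Kupffer cells and other macrophages were higher in EtOH than in CHO livers for 7 of 21 genes and lower for 0 (16 higher adjusted over the list alone, camera adjusted p = 1e-07, and adjusted p = 0.393 with an estimated correlation). Marco, C1qc and Cd5l differed by log2 1.00, 0.60 and 0.94. Sinusoidal endothelial markers were higher for 2 of 17 (4 adjusted over the list alone, camera adjusted p = 0.0156, and adjusted p = 0.541 with an estimated correlation), and the set was not called with the block by cohort and replicate number (list mean 0.107, camera adjusted p = 0.0789). Of 23 genes for proteins that hepatocytes secrete, 1 was higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.878, and adjusted p = 0.93 with an estimated correlation). Pericentral hepatocyte markers were lower for 8 of 16 genes and higher for 1 (9 and 3 adjusted over the list alone, camera adjusted p = 0.000998, and adjusted p = 0.213 with an estimated correlation). Among them Rgn was lower, at log2 -0.67, and Slc1a2 at -1.28. Mitosis genes were already somewhat higher in EtOH control livers, with 11 of 41 members called and a list mean of 0.28 (22 higher and 1 lower adjusted over the list alone, camera adjusted p = 9.52e-08, and adjusted p = 0.393 with an estimated correlation). Mean levels of the members Racgap1, Ndc80 and Prc1 lay under the array medians in each diet (4.38, 3.88 and 4.19 in EtOH livers, lower in CHO and HF). That of Cdc20 was 5.09 in EtOH and 4.59 in CHO livers. Ccnb1 was higher by log2 0.72, next to 1.85 ± 0.17 for Cdkn1a and a lower Ccnd1 (-0.92), the cyclin of early G1. Cyp2b1 stood at a mean level of 8.20 against 5.15 in CHO (log2 difference 3.22 ± 0.36), and Cyp2b2 differed by 2.50. The cytochrome list as a whole had 9 of 31 members higher and 3 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.0155, and adjusted p = 0.393 with an estimated correlation). Cyp2e1, the ethanol-oxidising cytochrome, was slightly lower in EtOH livers (log2 -0.22 ± 0.073, adjusted p = 0.0441), a call that ended with all 72 arrays (-0.131), with weighted arrays (-0.192), after renewed quantile normalization (-0.222) and, at -0.24 to -0.194, without any 1 of 12 animals (EtOH 1 h replicates 1, 3 and 4, EtOH 6 h replicate 4, EtOH 24 h replicates 1 and 4, CHO 1 h replicates 1, 2 and 4, CHO 6 h replicate 3, and CHO 24 h replicates 2 and 4). Cyp7a1 was lower, at log2 -1.95 ± 0.38. Stac3 (probe set 10895915) was lower, at log2 -4.25 ± 0.35, and Car3, a carbonic anhydrase, at -3.07. The scan day was held constant in these counts. Without it 2947 genes differed, and within the animals of the 1, 6 and 24 h cohorts alone, which leaves fewer arrays, 183, 424 and 133 did. In 1 or more of these cohorts alone, calls ended for Per1, Tm7sf2, Pmvk, Cd36, Marco, C1qc, Cd5l, Rgn, Slc1a2, Ccnb1, Cdkn1a, Ccnd1, Cyp2b1, Cyp2b2, Cyp2e1 and Cyp7a1, and for the endothelial, cytochrome and mitosis lists. With the misplaced CHO columns kept as named, they ended for Cyp7a1 (-1.384), Marco (0.88) and Ppara (-0.808).

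Against HF, 1937 genes differed (1066 higher and 871 lower in EtOH). The clock genes again stood out, with 5 of 17 higher and 10 lower (5 and 11 adjusted over the list alone, camera adjusted p = 3.88e-06, and adjusted p = 0.0457 with an estimated correlation). Scd differed by log2 4.67 ± 0.32, at mean levels of 10.29 in EtOH, 9.36 in CHO and 5.52 in HF livers. Fatty acid synthesis genes were higher for 11 of 21 members and lower for 0 (12 higher adjusted over the list alone, camera adjusted p = 2.32e-09, and adjusted p = 0.141 with an estimated correlation), Fasn among them by 1.41 and Gpam by 1.75. The sterol exporters Abcg5 and Abcg8 were lower, at log2 -3.14 and -2.46. Amino acid and urea metabolism had 11 of 24 higher (13 adjusted over the list alone, camera adjusted p = 8.16e-08, and adjusted p = 0.179 with an estimated correlation), with Ass1 at 0.62. Periportal markers were higher for 9 of 15 (9 adjusted over the list alone, camera adjusted p = 3.72e-07, and adjusted p = 0.084 with an estimated correlation). Macrophage markers were higher for 11 of 21 (14 adjusted over the list alone, camera adjusted p = 1.05e-07, and adjusted p = 0.45 with an estimated correlation), Marco by 1.16. Mitosis genes were higher for 17 of 41 (24 higher and 1 lower adjusted over the list alone, camera adjusted p = 9.15e-08, and adjusted p = 0.45 with an estimated correlation). Some of them, such as Ndc80 (3.88 in EtOH and 3.44 in HF livers), stood at levels under the array medians. Cdkn1a, Cyp2b1 and Cyp7a1 differed by 1.81, 2.83 and -1.85. Within the animals of a single cohort, which leaves fewer arrays, 164 genes were higher and 119 lower in the 1 h cohort, 626 differed in the 6 h cohort and 219 in the 24 h cohort, and in 1 or more cohorts calls ended for Fasn, Ass1, Marco, Cyp2b1 and Cyp7a1 and for the macrophage and mitosis lists.

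**Figure D1:**
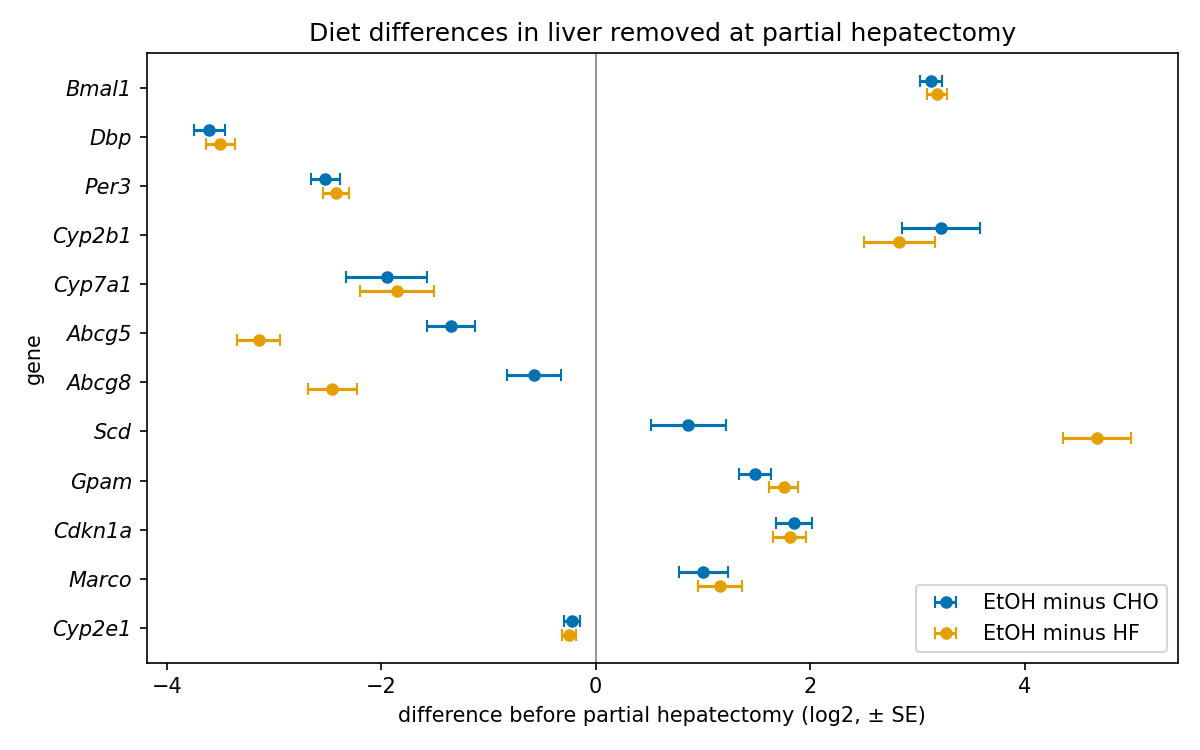
Difference in log2 expression (x axis, ± SE) between EtOH and CHO livers (blue) and between EtOH and HF livers (orange) before PHx, for 12 genes (y axis). Bmal1 lies at log2 3.13 and 3.18, Dbp at -3.60 and -3.50, and Scd differs from HF (4.67) far more than from CHO (0.865).

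Few genes differed between the control diets before surgery. Between HF and CHO livers, 24 genes differed (10 higher and 14 lower in HF). Abcg5 and Abcg8 were higher in HF livers by log2 1.79 ± 0.23 and 1.88 ± 0.26. Scd was lower, at -3.81 ± 0.36, and so were the fructose transporter gene Slc2a5 (-1.51) and the glycolytic gene Pklr (-1.10). Gluconeogenesis and glucose handling genes lay lower in HF (list mean -0.23, 0 of 18 called and 7 adjusted over the list alone, camera adjusted p = 6.66e-09, and adjusted p = 0.0013 with an estimated correlation). So did periportal hepatocyte markers (list mean -0.25, 0 of 15 called and 5 adjusted over the list alone, camera adjusted p = 2.3e-08, and adjusted p = 0.0426 with an estimated correlation). Fatty acid synthesis had 3 of 21 members lower (6 adjusted over the list alone, camera adjusted p = 8.95e-10, and adjusted p = 0.149 with an estimated correlation). Cholesterol synthesis lay higher in HF by a list mean of 0.43, with 0 of 20 members called (12 adjusted over the list alone, camera adjusted p = 8.9e-14, and adjusted p = 0.227 with an estimated correlation). Without CHO 1 h replicate 2, 6 genes were called in place of 24, with no scan-day block 82, and with the block by cohort and replicate number 54. With the misplaced CHO columns kept as named, 4 genes were called, Slc2a5 (-1.027) and Pklr (-0.872) were no longer called, and the fatty acid synthesis mean was -0.281. Within single cohorts, which leaves fewer arrays, the calls of Abcg5, Abcg8, Slc2a5 and Pklr ended in each cohort and that of Scd in the 6 and 24 h cohorts, and the cholesterol synthesis set was not called in the 6 h cohort (0.11).

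Within 1 h of PHx the remnant showed an early-response programme. Nr4a1 (probe set 10899387), an immediate early nuclear receptor, rose by log2 3.25 ± 0.19 SE from control levels under the array medians (in 10 of 10 pairs, adjusted p = 2.65e-12). Igfbp1, a secreted insulin-like growth factor binding protein, rose 9.48-fold (log2 3.25 ± 0.32). Immediate early genes, inflammatory genes, glucocorticoid targets and gluconeogenic genes were each called as sets that rose. The members called were 29 of 34, 11 of 24, 12 of 14 and 7 of 18. In the mean of the 3 diets, 1485 genes changed (640 rose and 845 fell). By at least 1.5-fold, 216 rose and 52 fell.

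Of 34 immediate early genes, 29 rose and 0 fell (31 and 1 adjusted over the list alone, camera adjusted p = 3.11e-54, and adjusted p = 7.58e-08 with an estimated correlation). Atf3 rose by log2 2.81, Egr1 by 2.59, Gadd45b by 2.43, Myc by 2.05 ± 0.21 and Fos by 0.79 ± 0.091. Apold1 and Noct rose by 3.06 and 2.75. Inflammatory genes of the NF-kB list rose for 11 of 24 members and fell for 0 (14 rose adjusted over the list alone, camera adjusted p = 1.27e-15, and adjusted p = 0.000181 with an estimated correlation). The neutrophil attractant Cxcl1 rose by log2 2.18, the interleukin 1 genes Il1rn and Il1a by 1.94 and 1.44, and Nfkbiz by 1.54. Neutrophil markers were not called in either direction (0 of 13 in limma, also when adjusted over the list alone, camera adjusted p = 0.126, and adjusted p = 0.362 with an estimated correlation). Glucocorticoid targets rose for 12 of 14 genes (12 adjusted over the list alone, camera adjusted p = 7.29e-14, and adjusted p = 0.00191 with an estimated correlation), among them Sgk1 (1.42), Dusp1 (1.37) and Per1 (1.09). Gluconeogenesis and glucose handling genes rose for 7 of 18 (10 rose and 2 fell adjusted over the list alone, camera adjusted p = 1.48e-05, and adjusted p = 0.0289 with an estimated correlation). Ppargc1a, the coactivator that switches on gluconeogenesis, rose by log2 2.17 ± 0.11.

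Macrophage markers rose slightly for 11 of 21 genes at 1 h (list mean 0.24, 18 adjusted over the list alone, camera adjusted p = 1.7e-11, and adjusted p = 0.113 with an estimated correlation), for instance Ctss by 0.38 and C1qc by 0.32. Sinusoidal endothelial markers rose for 6 of 17 (8 adjusted over the list alone, camera adjusted p = 1.8e-05, and adjusted p = 0.143 with an estimated correlation), Lyve1 by 0.50. Ribosome biogenesis genes rose for 8 of 37 (9 adjusted over the list alone, camera adjusted p = 1.05e-06, and adjusted p = 0.379 with an estimated correlation). Of 41 mitosis genes 0 rose and 2 fell (1 adjusted over the list alone, camera adjusted p = 0.0999, and adjusted p = 0.584 with an estimated correlation), and after renewed quantile normalization the set was called (list mean -0.083, camera adjusted p = 0.0476). Marked decreases were those of the transcription factor Snai2 (-1.63 ± 0.15), Rtp3 (-1.24), the lipogenic regulator Mid1ip1 (-1.06) and the hepatocyte factor Foxa2 (-1.02). Within the animals of scan day 8 alone, which leaves fewer pairs, 475 genes were called in place of 1485, and not Ctss, C1qc and Lyve1. C1qc was not called within scan day 7 either.

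At 6 h, 37 of 37 ribosome biogenesis and 22 of 30 acute phase genes rose and 20 of 20 cholesterol synthesis genes fell. The calls of these sets were lost with an estimated correlation (adjusted p = 0.0615, 0.0615 and 0.153). Lcn2 (probe set 10844331), an iron-binding acute phase protein, rose 67.8-fold (log2 6.08 ± 0.15, adjusted p = 2.47e-20), and A2m (probe set 10858408), the acute phase protease inhibitor of the rat, rose 63.5-fold (log2 5.99 ± 0.20), both in 9 of 9 pairs. Changes passed the threshold for 5804 genes (2913 rose and 2891 fell), and 2265 reached 1.5-fold.

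Ribosome biogenesis genes rose for 37 of 37 (37 adjusted over the list alone), by a mean of log2 1.45, with Npm1 at 1.42 ± 0.067, Mrto4 at 1.36 and Mybbp1a at 2.28 (camera adjusted p = 1.11e-29, and adjusted p = 0.0615 with an estimated correlation). Acute phase genes rose for 22 of 30 and fell for 2 (22 and 3 adjusted over the list alone, camera adjusted p = 3.81e-11, and adjusted p = 0.0615 with an estimated correlation). Osmr, the oncostatin M receptor, rose by log2 3.36 and Socs3, the feedback inhibitor of STAT3 signalling, by 3.14. NF-kB genes rose for 11 of 24 (13 adjusted over the list alone, camera adjusted p = 0.000161, and adjusted p = 0.0615 with an estimated correlation), led by Cxcl1 at 4.74. Immediate early genes rose for 20 of 34, and 3 fell (20 and 3 adjusted over the list alone, camera adjusted p = 0.00102, and adjusted p = 0.0958 with an estimated correlation), with Junb at 1.94. The citrate transporter gene Slc13a5 rose by 4.15, Tnfrsf21 by 4.10 and the transglutaminase gene Tgm1 by 3.93.

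Cholesterol synthesis genes fell for 20 of 20 at 6 h (20 adjusted over the list alone, list mean -0.98, camera adjusted p = 1.39e-10, and adjusted p = 0.153 with an estimated correlation), Msmo1 at log2 -2.16, Fdft1 at -1.68 and Nsdhl at -1.11. Fatty acid synthesis genes fell for 17 of 21 and 1 rose (18 and 2 adjusted over the list alone, camera adjusted p = 1.78e-08, and adjusted p = 0.0768 with an estimated correlation), with Gpam at -2.01, Acacb at -1.86 and Fasn at -0.77. Bile acid synthesis and transport genes fell for 15 of 22 (17 adjusted over the list alone, camera adjusted p = 3.69e-07, and adjusted p = 0.0615 with an estimated correlation). Cyp7a1 fell by log2 3.53 ± 0.30, and the canalicular exporter Abcc2 fell by 1.52. All 9 of 9 ethanol metabolism genes fell (9 adjusted over the list alone, camera adjusted p = 4.78e-06, and adjusted p = 0.0615 with an estimated correlation), Cat at -0.92, Aldh2 at -0.53 and Cyp2e1 at -0.26, the last not past the threshold without HF 6 h replicate 3 (-0.246) or within scan day 1 alone (-0.286). Drug-metabolising cytochromes fell for 22 of 31 and 3 rose (23 and 3 adjusted over the list alone, camera adjusted p = 1.11e-06, and adjusted p = 0.0958 with an estimated correlation). Ppara fell by log2 3.15 ± 0.17, while its targets split, with 12 of 33 rising and 13 falling (12 and 14 adjusted over the list alone, camera adjusted p = 0.518, and adjusted p = 0.958 with an estimated correlation). Interferon response genes fell for 15 of 26 and 2 rose (16 and 2 adjusted over the list alone, camera adjusted p = 0.0089, and adjusted p = 0.583 with an estimated correlation). Endothelial markers rose for 10 of 17 and fell for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.025, and adjusted p = 0.544 with an estimated correlation), a set not called without the animal block (list mean 0.206), with all 72 arrays (0.176) or with dim genes left out (0.224). Secreted hepatocyte proteins fell for 15 of 23 and rose for 1 (16 and 1 adjusted over the list alone, camera adjusted p = 0.000512, and adjusted p = 0.311 with an estimated correlation).

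At 24 h, 39 of 41 mitosis genes and 33 of 36 genes of G1 and DNA replication rose in the mean of the diets (adjusted p = 1.93e-05 and 0.036 with an estimated correlation). The mean covers unlike responses, since the mitosis list rose by 0.591 in EtOH against 2.814 in CHO and 2.551 in HF livers. The values of single genes that follow are such means too. Ccnb1 (probe set 10821016), the mitotic cyclin, rose by log2 3.10 ± 0.085, from control levels under the array medians in CHO and HF livers, Cdk1, its kinase, by log2 2.89 ± 0.083, and Rrm2, a subunit of the enzyme that makes deoxynucleotides, by 4.76 ± 0.13, each in 8 of 8 pairs. Over the control livers of all cohorts, Cdk1 also stood under the array medians in each diet (3.78, 3.44 and 3.41 in EtOH, CHO and HF). So did Rrm2 in CHO and HF livers (4.41 and 4.42). A2m and Lcn2 were raised by log2 6.73 and 6.65. Changes passed the threshold for 4956 genes (2405 rose and 2551 fell), and 1373 reached 1.5-fold. In the 6 and 24 h cohorts, which are different animals, 3286 genes were called in both, of which 1327 rose in both, 1543 fell in both and 416 changed in opposite directions.

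Mitosis genes rose for 39 of 41 (39 adjusted over the list alone, camera adjusted p = 1.16e-53, and adjusted p = 1.93e-05 with an estimated correlation), by a list mean of log2 1.99, Top2a by 3.79, Pbk by 3.99 and Ect2 by 2.94. G1 and DNA replication genes rose for 33 of 36 (34 adjusted over the list alone, camera adjusted p = 1.25e-28, and adjusted p = 0.036 with an estimated correlation), with Pcna at 2.53 ± 0.16 and Prim1 at 2.06. Rrm1 rose by 2.06, whereas its other probe set gave 0.23. Ccnd1 differed from the controls by -0.32 (adjusted p = 0.139), and at -0.502 and -0.51, past the threshold, without HF 24 h replicate 2 or CHO 24 h replicate 2. With all 72 arrays it differed by -0.081. Acute phase genes rose for 19 of 30 and fell for 4 (20 and 4 adjusted over the list alone, camera adjusted p = 1.91e-10, and adjusted p = 0.036 with an estimated correlation). Ribosome biogenesis genes rose for 21 of 37 (24 adjusted over the list alone, camera adjusted p = 3.85e-08, and adjusted p = 0.325 with an estimated correlation), at a list mean of 0.41.

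Cytochromes of drug metabolism fell for 23 of 31 at 24 h and 3 rose (24 and 3 adjusted over the list alone, camera adjusted p = 1.36e-11, and adjusted p = 0.036 with an estimated correlation), Cyp2c23 at log2 -1.56. Bile acid genes fell for 15 of 22 and 1 rose (15 and 2 adjusted over the list alone, camera adjusted p = 3.78e-07, and adjusted p = 0.036 with an estimated correlation), with the uptake transporter Slc10a1 at -1.67. Ethanol metabolism fell for 8 of 9 (8 adjusted over the list alone, camera adjusted p = 6.11e-07, and adjusted p = 0.036 with an estimated correlation), Cat at -1.20 and Cyp2e1 at -0.82. Fatty acid synthesis fell for 16 of 21 and 2 rose (17 and 2 adjusted over the list alone, camera adjusted p = 1.32e-08, and adjusted p = 0.0595 with an estimated correlation), Fads2 at -2.12 and Thrsp at -2.23. Periportal markers fell for 11 of 15 (11 adjusted over the list alone, camera adjusted p = 0.000199, and adjusted p = 0.172 with an estimated correlation), and secreted hepatocyte proteins for 15 of 23, with 1 that rose (15 and 1 adjusted over the list alone, camera adjusted p = 5.32e-07, and adjusted p = 0.118 with an estimated correlation). Marked decreases were those of Aox3 (-3.57), Inmt (-3.34) and Nrep (-3.22), and Serpina6, the corticosteroid binding globulin, fell by 2.98. Macrophage markers went both ways, with 6 of 21 rising and 7 falling (7 and 7 adjusted over the list alone, camera adjusted p = 0.67, and adjusted p = 0.904 with an estimated correlation), Marco by 1.41 and Clec4f, a marker of resident Kupffer cells, at -0.48. Within the animals of scan day 4 alone, which leaves fewer pairs, 2264 genes were called in place of 4956.

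**Figure D2:**
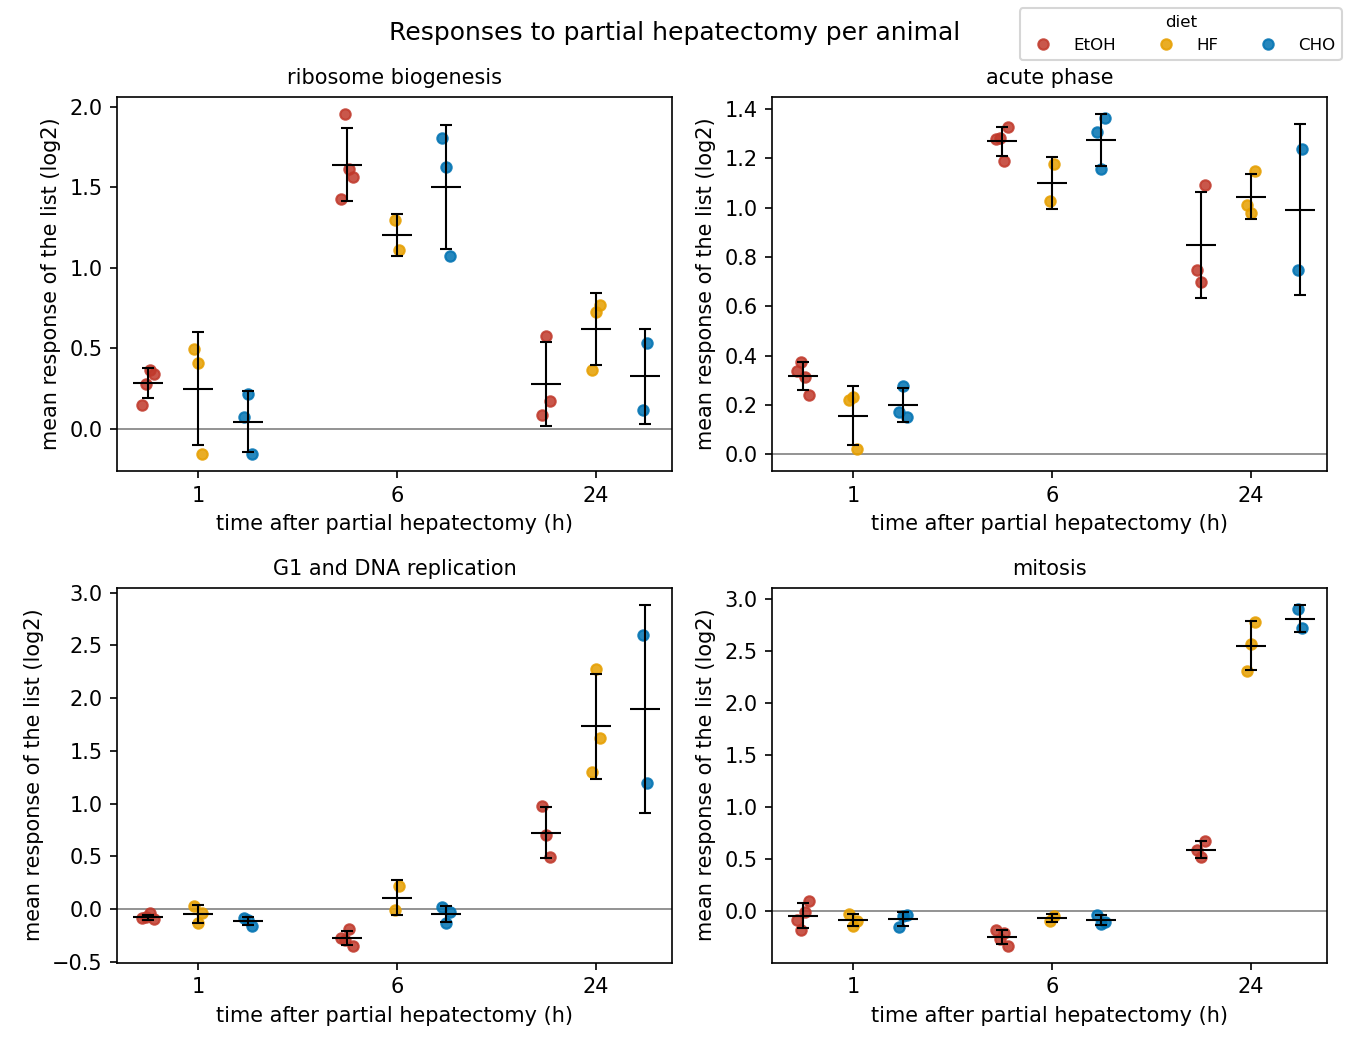
Mean log2 response (y axis) of 4 gene lists at 1, 6 and 24 h after PHx (x axis), 1 point per animal coloured by diet, with the mean ± SD of each group in black. Each time is a different cohort. Ribosome biogenesis at 6 h averages 1.641 in EtOH, 1.204 in HF and 1.502 in CHO livers, and mitosis genes at 24 h average 0.59 in EtOH against 2.55 in HF and 2.81 in CHO livers.

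The response was also counted in each diet on its own. At 1 h, 422 genes changed in EtOH and 299 in HF livers, and in CHO livers 182 rose and 103 fell. At 6 h, the counts were 5010, 2806 and 4232, with 4 EtOH, 2 HF and 3 CHO pairs behind them. At 24 h, they were 2074, 3637 and 2431, with 3, 3 and 2 pairs. For HF at 6 and 24 h, which are different cohorts, counts were 4085 and 3508 with all 72 arrays and 3410 and 2964 with weighted arrays. Weighted arrays also gave 727, 467 and 607 genes in EtOH, HF and CHO livers at 1 h, and 1148 and 1421 in EtOH and CHO livers at 24 h. With all 72 arrays, 179 genes rose and 95 fell in EtOH livers at 1 h. The correlation of the mean responses across genes, which are not independent replicates, was 0.899 between HF and CHO at 24 h, against 0.623 between EtOH and CHO and 0.676 between EtOH and HF. At 6 h it was 0.895, 0.848 and 0.786 in the same order, and at 1 h 0.702, 0.692 and 0.693. Single animals moved these counts. For HF at 6 h and CHO at 24 h, leaving out 1 animal leaves 1 pair, assumed to vary like the other groups. At 1 h, 223 and 220 genes were called in EtOH livers without replicate 2 or 3, 119 and 95 in HF livers without replicate 1 or 2, and 149, 120 and 132 in CHO livers without replicate 1, 2 or 4. At 6 h, 1218 and 1702 were called in HF livers without replicate 3 or 4. At 24 h, 1114 were called in EtOH livers without replicate 1 and 1405 in CHO livers without replicate 4.

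**Figure D3:**
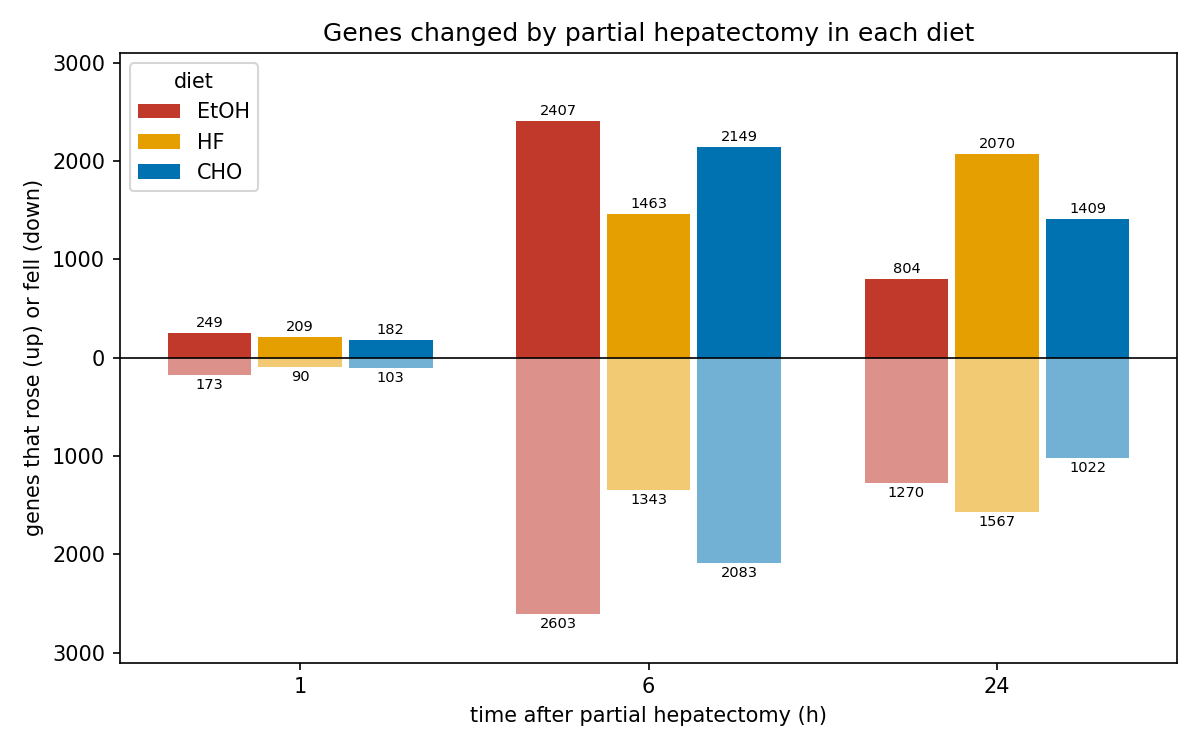
Number of genes that rose (upper bars) or fell (lower bars) after PHx in each diet (y axis) at 1, 6 and 24 h (x axis). At 24 h, 804 genes rose in EtOH livers against 2070 in HF and 1409 in CHO livers.

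At 1 h no single gene was shown to respond differently in ethanol-fed rats. In limma 0 genes differed between EtOH and CHO in their response (534 at an unadjusted p under 0.05), and 0 between EtOH and HF (475 unadjusted). As sets, cholesterol synthesis genes lay lower in the EtOH response, with a list mean of -0.33 against CHO (camera adjusted p = 3.66e-05, and adjusted p = 0.953 with an estimated correlation) and -0.35 against HF (camera adjusted p = 8.15e-06, and adjusted p = 0.691 with an estimated correlation, and a list mean of -0.227 without the animal block). Of their 20 members 0 were called against either diet, also when adjusted over the list alone. Ribosome biogenesis genes lay higher in EtOH than in CHO (list mean 0.24, camera adjusted p = 1.38e-07, and adjusted p = 0.953 with an estimated correlation), with 0 of 37 called, also when adjusted over the list alone. Across genes, the differences from CHO and from HF, which share the EtOH animals, correlated at 0.486, against 0.429 simulated without any effect, and at 0.0761 on average (-0.0658 to 0.157) when different EtOH animals entered each. In simulated data with these animals, 83.6% of genes with a difference of log2 1 were recovered and 19.4% of those with 0.5.

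At 6 h single genes of the clock and of lipid and sterol metabolism responded differently in ethanol-fed rats. Nr1d1, the clock repressor REV-ERBa, changed by a mean of 0.77 ± 0.41 (SD, n = 4) in EtOH livers against -2.94 ± 0.89 (n = 3) in CHO and -2.62 (n = 2) in HF livers (EtOH minus CHO 3.71 ± 0.42 SE, adjusted p = 1.42e-05). Pdk4, the kinase that holds back glucose oxidation, changed by -0.11 in EtOH against 3.55 in CHO and 3.23 in HF livers (difference from CHO -3.65 ± 0.42). Gpam and the sterol synthesis enzyme Msmo1 fell further in EtOH livers (differences from CHO -2.70 ± 0.31 and -2.59 ± 0.36). These are differences in the change, not in the level after PHx. Over the controls of all cohorts, Pdk4 stood at 9.18 in EtOH and 6.87 in CHO livers, and Gpam at 9.62 and 8.02.

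Between EtOH and CHO, 279 genes differed in response at 6 h (107 higher and 172 lower in EtOH). The cholesterol synthesis response was lower for 8 of 20 genes and higher for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 4.91e-14, and adjusted p = 0.532 with an estimated correlation), with Dhcr7 at -1.84 and Pmvk at -1.59. PPARa targets were lower for 7 of 33 (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.88e-11, and adjusted p = 0.532 with an estimated correlation). Among them Cyp4a1 differed by -1.57 and Angptl4, an inhibitor of lipoprotein lipase, by -2.71 ± 0.52. Clock genes were higher for 5 of 17 and lower for 4 (8 and 5 adjusted over the list alone, camera adjusted p = 0.251, and adjusted p = 0.718 with an estimated correlation), so that the list as a whole was not called. Dbp differed by 2.79 ± 0.39 and Bmal1 by -2.30 ± 0.35. Gluconeogenesis genes were higher for 3 of 18 and lower for 1 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0196, and adjusted p = 0.532 with an estimated correlation), Ppargc1a by 1.56. The response of Stac3 was higher by 3.80 ± 0.27 and that of Lpin1 by 3.00. Over the controls of all cohorts, Stac3 stood at 4.525 in EtOH and 8.73 in CHO livers, and Dbp at 6.93 and 10.51. The reverse offset held for Bmal1 (6.71 and 3.57), Dhcr7 (10.1 and 8.5) and Pmvk (8.15 and 6.69). Of the 279 genes, 89.2% had a baseline difference of the opposite sign in the other cohorts, against 55.2% of all genes. With the scan day in place of the animal as block 157 genes differed, with all 72 arrays 181, and with weighted arrays 462. Without EtOH 6 h replicate 2 or CHO 6 h replicate 3, 154 or 135 differed, and without the latter Lpin1 (2.78) was no longer called.

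Between EtOH and HF, 293 genes differed at 6 h (83 higher and 210 lower in EtOH), from 2 HF pairs. Of these, 47 were higher and 89 lower in both comparisons, against 0.6 and 2.5 for independent lists. The response of Pdk4 was lower, at -3.33, a call lost with all 72 arrays (-2.439, adjusted p = 0.0809), and those of Nr1d1 and Stac3 higher by 3.39 and 3.37. Over the controls of all cohorts, Pdk4 stood at 9.18 in EtOH and 6.68 in HF livers, and Stac3 at 4.525 and 7.6. A baseline difference of the opposite sign in the other cohorts was found for 84.6% of the 293 genes, against 57.4% of all genes. Cholesterol synthesis was lower for 5 of 20 and higher for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 1.34e-08, and adjusted p = 0.383 with an estimated correlation), with Msmo1 at -2.37. Fatty acid synthesis was lower for 4 of 21 (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 7.6e-05, and adjusted p = 0.383 with an estimated correlation), Gpam at -2.98. PPARa targets were lower for 3 of 33 (7 adjusted over the list alone, camera adjusted p = 5.23e-09, and adjusted p = 0.383 with an estimated correlation), the lipid droplet gene Plin2 at -1.94. Ribosome biogenesis rose further in EtOH for 3 of 37 (7 adjusted over the list alone, camera adjusted p = 8.41e-08, and adjusted p = 0.405 with an estimated correlation). Clock genes were higher for 6 of 17 and lower for 4 (6 and 5 adjusted over the list alone, camera adjusted p = 0.257, and adjusted p = 0.565 with an estimated correlation), Cry1 at -1.76. Both comparisons share the EtOH animals. Their differences correlated at 0.725 across genes, against 0.388 simulated without any effect (covariance 0.0758 against 0.0178), and at 0.532 on average when 2 EtOH animals were set against CHO and the other 2 against HF (0.438 to 0.587 over 6 such divisions, mean covariance 0.0624). With all 72 arrays 138 genes differed, and with weighted arrays 615. Without HF 6 h replicate 3 or 4, each of which leaves 1 HF pair assumed to vary like the other groups, 63 or 73 differed, and without EtOH 6 h replicate 2, 166. Plin2 (-1.13) was not called without HF replicate 3, nor was Msmo1 (-2.05) without HF replicate 4.

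**Figure D4:**
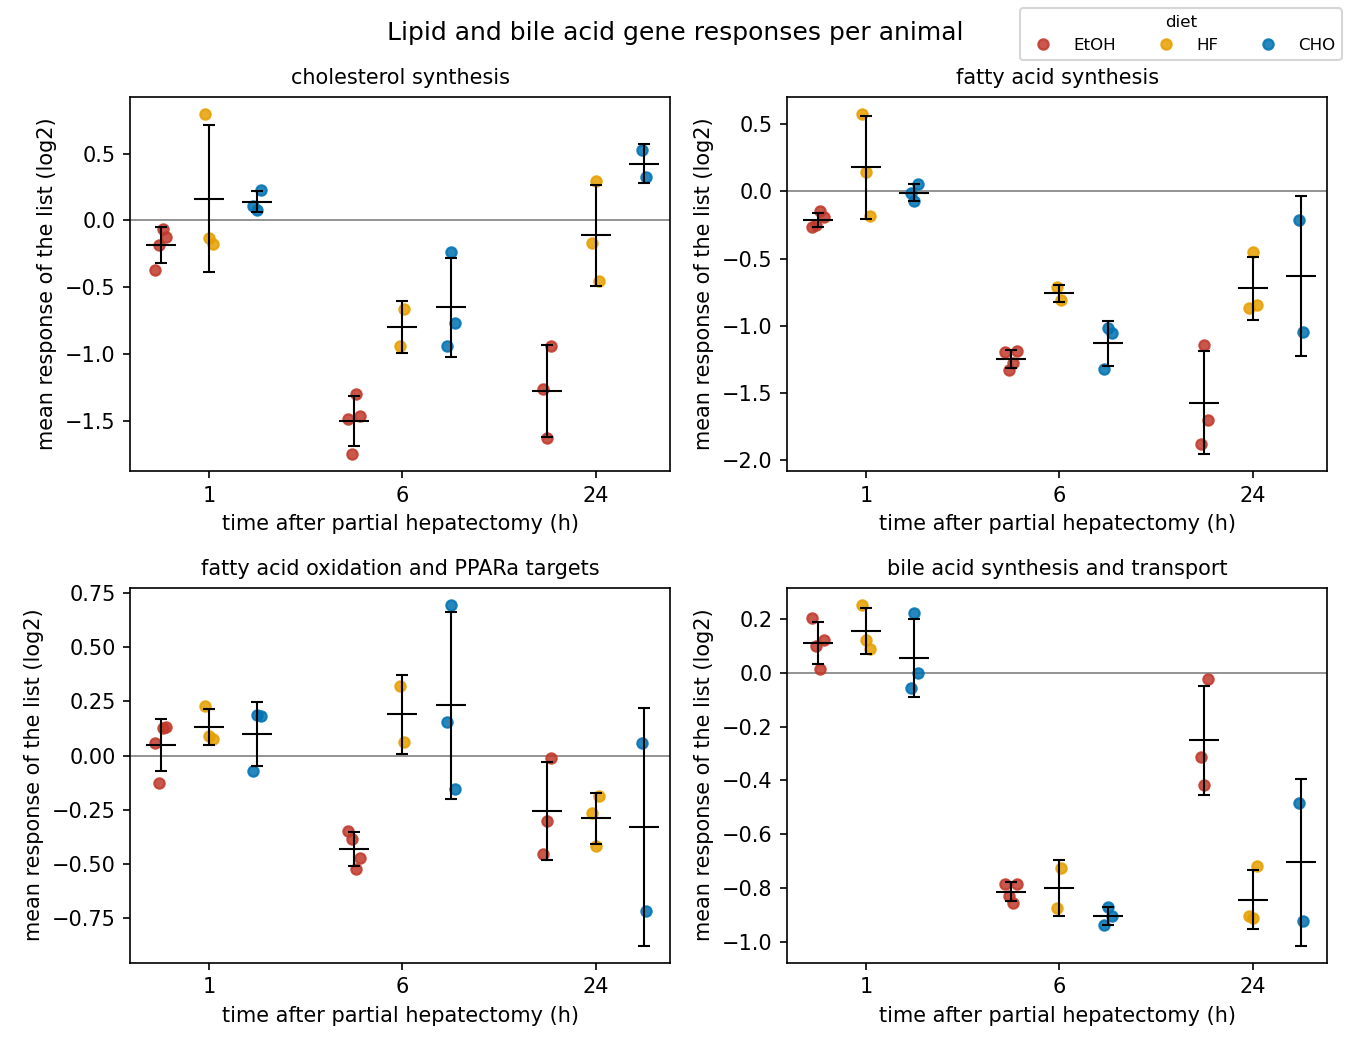
Mean log2 response (y axis) of 4 lipid and bile acid gene lists at 1, 6 and 24 h after PHx (x axis), 1 point per animal coloured by diet, with the mean ± SD of each group in black. The cholesterol synthesis mean in EtOH livers is -1.50 at 6 h and -1.275 at 24 h, when CHO livers average 0.43 and HF livers -0.11.

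At 24 h mitosis genes rose far less in ethanol-fed rats than in the control diets. Ccnb1 rose by a mean of 0.61 ± 0.33 (SD, n = 3) in EtOH livers against 4.50 ± 0.43 (n = 2) in CHO and 4.21 ± 0.22 (n = 3) in HF livers. The difference from CHO was log2 -3.89 ± 0.22 SE (adjusted p = 8.3e-12) and from HF -3.60 ± 0.19 (adjusted p = 3.75e-12). The mitosis list rose by 0.587, 0.515 and 0.672 in the 3 EtOH animals, by 2.91 and 2.72 in the CHO animals, and by 2.31, 2.57 and 2.78 in the HF animals. The mean response of cholesterol synthesis genes was -1.275 in EtOH, -0.11 in HF and 0.43 in CHO livers, and that of acute phase genes 0.847, 1.05 and 0.992.

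Between EtOH and CHO, 440 genes differed in response at 24 h (75 higher and 365 lower in EtOH). Of 41 mitosis genes, 37 rose less in EtOH (38 adjusted over the list alone, list mean -2.22, camera adjusted p = 1.52e-99, and adjusted p = 1.87e-07 with an estimated correlation). Top2a differed by -3.64 ± 0.26, Plk1 by -3.27, Bub1 by -2.80 and Cdk1 by -2.70 ± 0.21, which still rose by 1.07 in EtOH livers. G1 and DNA replication genes were lower for 19 of 36 (30 lower and 1 higher adjusted over the list alone, camera adjusted p = 7.35e-24, and adjusted p = 0.128 with an estimated correlation), Rrm2 at -3.62 ± 0.34 and Orc6 at -1.58. Cholesterol synthesis was lower for 17 of 20 (19 adjusted over the list alone, list mean -1.70, camera adjusted p = 3.92e-29, and adjusted p = 0.0251 with an estimated correlation). Sqle, the squalene epoxidase, changed by -1.76 in EtOH, 1.25 in CHO and 0.085 in HF livers (EtOH minus CHO -3.01 ± 0.40), and Dhcr7 differed by -2.42. Fatty acid synthesis was lower for 6 of 21 (9 adjusted over the list alone, camera adjusted p = 5.23e-08, and adjusted p = 0.128 with an estimated correlation). Interferon response genes were lower for 2 of 26 (12 adjusted over the list alone, camera adjusted p = 3.64e-07, and adjusted p = 0.247 with an estimated correlation), the immunoproteasome gene Psmb9 at -1.52, and the list mean of -0.65 was -0.384 with all 72 arrays. Clock genes were higher for 5 of 17 and lower for 1 (7 and 3 adjusted over the list alone, camera adjusted p = 0.00244, and adjusted p = 0.128 with an estimated correlation), a set not called with all 72 arrays (list mean 0.295, camera adjusted p = 0.193). The response of Stac3 was higher by 3.63, where controls of all cohorts stood at 4.525 in EtOH and 8.73 in CHO livers. A baseline difference of the opposite sign in the other cohorts was found for 72.7% of the 440 genes, against 51% of all genes. With weighted arrays 187 genes differed. Without CHO 24 h replicate 2, which leaves 1 CHO pair assumed to vary like the other groups, 225 genes differed, and Psmb9 (-1.055) was no longer called. Without EtOH 24 h replicate 1, 277 genes differed.

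Between EtOH and HF, 736 genes differed at 24 h (135 higher and 601 lower in EtOH, or 243 higher and 450 lower after the values were quantile-normalized again). Of 41 mitosis genes, 36 rose less in EtOH (36 adjusted over the list alone, list mean -1.96, camera adjusted p = 3.48e-85, and adjusted p = 6.34e-07 with an estimated correlation), Ccna2 at -3.20 and Cdk1 at -2.75. G1 and replication genes were lower for 20 of 36 (27 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.66e-18, and adjusted p = 0.158 with an estimated correlation), Rrm2 at -3.25. Cholesterol synthesis was lower for 16 of 20 (19 adjusted over the list alone, camera adjusted p = 2.56e-17, and adjusted p = 0.0893 with an estimated correlation), Fdft1 at -1.51, and fatty acid synthesis for 6 of 21 (11 adjusted over the list alone, camera adjusted p = 1.37e-06, and adjusted p = 0.158 with an estimated correlation), Fasn at -1.92. Bile acid genes were higher for 7 of 22 (8 adjusted over the list alone, camera adjusted p = 2.81e-06, and adjusted p = 0.0803 with an estimated correlation), with a list mean of 0.59, which was 0.329 with all 72 arrays. The response of Abcg5 differed by 2.84, where controls of all cohorts stood at 5.64 in EtOH and 8.82 in HF livers. A baseline difference of the opposite sign in the other cohorts was found for 77.3% of the 736 genes, against 53.7% of all genes. Clock genes were higher for 6 of 17 and lower for 3 (8 and 3 adjusted over the list alone, camera adjusted p = 2.99e-05, and adjusted p = 0.0546 with an estimated correlation), Dbp by 2.65. In both comparisons, 38 genes were higher and 301 lower in EtOH, against 0.7 and 15.1 for independent lists. The differences correlated at 0.826 across genes, against 0.454 simulated without any effect (covariance 0.121 against 0.0231). With 3 EtOH animals the group could not be divided in equal parts of at least 2, so the share of the excess that comes from the shared animals is open. With all 72 arrays 448 genes differed, and with weighted arrays 365. Without EtOH 24 h replicate 1 or 3, or without HF 24 h replicate 4, 405, 467 or 446 genes differed.

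Between HF and CHO no single gene was shown to respond differently. In limma 0 genes differed at 1, 6 and 24 h (436, 785 and 579 at an unadjusted p under 0.05). As a set, mitosis genes rose less in HF than in CHO at 24 h, with a list mean difference of -0.26, with 0 of 41 members called, also when adjusted over the list alone (camera adjusted p = 1.2e-09, and adjusted p = 0.2 with an estimated correlation). Cholesterol synthesis lay lower in HF at 24 h (list mean -0.54, 0 of 20 called, also when adjusted over the list alone, camera adjusted p = 5.5e-10, and adjusted p = 0.565 with an estimated correlation), and at -0.269 with all 72 arrays. At 6 h ribosome biogenesis lay lower in HF (list mean -0.30, 0 of 37 called, also when adjusted over the list alone, camera adjusted p = 2.35e-07, and adjusted p = 0.761 with an estimated correlation).

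The strength of the response was measured in each animal as its mean log2 change, signed by the HF response, over the genes called in the HF response at that time (299, 2806 and 3637 genes at 1, 6 and 24 h). A lower value can come from a weaker response or from one unlike that of HF animals. EtOH animals averaged 0.781 ± 0.076 (SD, n = 4), 0.831 ± 0.051 (n = 4) and 0.372 ± 0.093 (n = 3) at 1, 6 and 24 h, and CHO animals 0.856 ± 0.064 (n = 3), 0.919 ± 0.081 (n = 3) and 0.669 ± 0.057 (n = 2). The differences were -0.076, -0.088 and -0.297. An exact 2-sided permutation test within each time gave p = 0.257, 0.171 and 0.1, where 0.0286, 0.0286 and 0.1 are the smallest values these group sizes allow. Averaged over the 3 times, with diets exchanged within each time in all 12250 ways, the difference was -0.153 (exact permutation p = 0.0031). Over the 500 genes with the largest HF response, the differences at 1, 6 and 24 h were -0.029, -0.251 and -0.92, and -0.4 over all times. With all 72 arrays they were -0.092 at 1 h, -0.028 at 6 h and -0.191 at 24 h.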

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

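Of the tests in this part, those on mislabelling, scan days, acute phase genes, hepatocyte genes, the 2 arms of the clock and the misplaced columns were chosen after the result was seen, whereas the comparison of replication with mitosis genes and the regroupings of animals were fixed before.

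The response of mitosis genes at 24 h differed between EtOH and the other diets by a list mean of -2.22 against CHO and -1.96 against HF, a difference tested as such. EtOH 24 h replicate 4, whose tag reads high fat, is not among the animals behind these values, so a mislabelling of that animal cannot have produced them. Its own response over all 72 arrays was 0.686, next to group means of 0.591 in EtOH, 2.551 in HF and 2.814 in CHO animals of the fit. That is the value of a single animal. The scan day is argued against by a difference of -1.885 between EtOH and HF animals within scan day 4. An equal damping of every gene group is argued against by the acute phase genes, which reached 0.827 of the response of the other diets, while the mitosis genes reached 0.223. The smaller response was not confined to mitosis genes, since replication genes rose by 0.725 in EtOH, 1.896 in CHO and 1.731 in HF animals. Over the 3637 genes called in the HF response, mean strength was 0.372 in EtOH and 0.669 in CHO animals. These genes and their signs were chosen from the HF response and include 39 of 41 mitosis genes. The strength therefore does not show how far the smaller response reaches beyond mitosis genes. In each EtOH animal replication genes reached a larger share of the linear rise of the other diets than mitosis genes (0.284, 0.205 and 0.158 over 28 genes, against 0.067, 0.067 and 0.085 over 35 genes, smallest difference 0.073), so that a later entry into the cycle is a candidate explanation. A single late time point leaves open whether the cycle was delayed, halted or entered by fewer cells.

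Clock genes differed before PHx, with Bmal1 higher and its targets lower in EtOH livers. The scan day is argued against by the Bmal1 difference within 6 scan days, which was at least 2.81. Secreted hepatocyte protein genes differed by a mean of -0.041, which argues against a loss of hepatocytes as large as the difference of Dbp. A smaller change in the share of hepatocytes was not tested. Of 11 measured members of the activating and the driven arm, 10 differed in the directions that another phase of the daily rhythm would give and 0 in the other. Another phase at surgery may therefore underlie the difference, but the hour at which each liver was taken is not given, so a diet effect on the clock, a difference in feeding time and a difference in the hour of surgery stay open.

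Of the columns in the table without outliers, 2 CHO control columns carry PHx values. They correlated at 0.985 and 0.992 with the PHx arrays of the same animals in the batch-corrected table, against 0.276 and -0.365 with the controls of their own names. The PHx arrays thus stand under the control names. Both of these PHx arrays are marked as outliers, and the controls are not. An exchange of the arrays in every table is argued against, since the PHx minus control differences of these animals in the batch-corrected table correlated at 0.617 and 0.857 with the mean response of the other CHO animals. No biological explanation was tested.

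The response to PHx differed between diets for 279 genes (EtOH minus CHO, 6 h), 440 (24 h), 293 (EtOH minus HF, 6 h) and 736 (24 h), and cholesterol synthesis differed between EtOH and CHO at 24 h by a list mean of -1.70. Probe sets with no annotated gene also responded to PHx, 538 of 13581 at 1 h, 2375 at 6 h and 2175 at 24 h. In animals left out for an outlier array, mitosis responses at 24 h were 3.08 and 2.74 in CHO replicates 1 and 3, 2.68 in HF replicate 3 and 0.686 in EtOH replicate 4.

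Single samples stood apart in 5 of 140 groups, where chance gives about 7. Before PHx, PPARa targets had a mean level of 8.69 in HF 6 h replicate 4 (nearest other 8.88), ethanol metabolism genes 9.82 in CHO 6 h replicate 2 (9.99), periportal markers 10.07 in CHO 1 h replicate 2 (9.86) and endothelial markers 6.81 in CHO 6 h replicate 2 (6.70). The cytochrome response at 1 h was 0.11 in EtOH replicate 1 (nearest other -0.007).

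Regrouping the animals tests whether chance would give as many genes. No other regrouping called as many genes for the mean response at 1 h (1485 genes, at most 572 in the other 99 of 100 regroupings), 6 h (5804, at most 4178) and 24 h (4956, at most 4066). The same held for EtOH minus CHO at 6 h (279, at most 31, 1 of 35 regroupings, the smallest share possible there). It also held for the baseline comparisons of EtOH with CHO (1719, at most 6), EtOH with HF (1937, at most 775) and HF with CHO (24, at most 9). Chance is thereby less likely but not excluded, since the shares were not adjusted for the number of comparisons regrouped. For EtOH minus CHO and EtOH minus HF at 1 h (0 genes each in limma, 534 and 475 unadjusted, others at most 1) and HF minus CHO at 1 h (0 in limma, 436 unadjusted, others at most 0), no regrouping can give fewer, so the test says nothing about chance. Regroupings are too few for EtOH alone at 1, 6 and 24 h (422, 5010 and 2074, others at most 0, 1 and 1), CHO at 1 and 6 h (182 risen and 103 fallen genes, and 4232 genes, others at most 1 and 0), HF at 1 and 24 h (299 and 3637, at most 1 and 2) and EtOH minus HF at 24 h (736, at most 104, 10 regroupings). Comparisons with 2 animals in a diet were not regrouped.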

How the results depend on the processing

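Among the alternatives, keeping the 2 misplaced CHO control columns as named was chosen after seeing the data, and all others before. Of the named genes, 1706 results across alternatives other than leaving an animal out stayed on the same side of the threshold, 69 lost the call, 0 gained it and 0 turned direction, and for lists these counts were 788, 17, 1 and 0. Leaving out 1 animal ended 17 calls of named genes and made 2, each given beside the gene. Where no cause is stated below, the cause was not tested.

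Without the animal as block (scan day in its place, no pairing), EtOH minus CHO at 6 h gave 157 genes in place of 279. The block by cohort and replicate number gave 54 genes for HF minus CHO at baseline in place of 24. With no block and no scan day, 2947 genes differed between EtOH and CHO (1719 before) and 82 between HF and CHO. Fewer arrays entered the cohorts taken alone, where 183, 424 and 133 genes differed between EtOH and CHO at baseline (1, 6 and 24 h cohorts), 2.8e+02 (164 higher and 119 lower), 626 and 219 between EtOH and HF (1937 before), and 2, 0 and 0 between HF and CHO. Likewise, with fewer pairs, scan day 8 alone gave 475 genes for the mean response at 1 h (1485 before) and scan day 4 alone 2264 at 24 h (4956 before). The other 3 scan days (3, 5 and 6) held too few pairs.

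With all 72 arrays, counts were 2.7e+02 for EtOH at 1 h (179 risen and 95 fallen, 422 before), 181 and 138 for EtOH minus CHO and EtOH minus HF at 6 h (279 and 293), 448 for EtOH minus HF at 24 h (736), and 42 for HF minus CHO at baseline. With weighted arrays they were 727 and 1148 for EtOH at 1 and 24 h (422 and 2074), 607 and 1421 for CHO at these times (the second 2431 before), 467 for HF at 1 h (299), 462 and 187 for EtOH minus CHO at 6 and 24 h (279 and 440), and 615 and 365 for EtOH minus HF (293 and 736). With a trended robust prior, 2 genes differed between HF and CHO at 6 h in place of 0. With the misplaced columns kept, 4 did at baseline in place of 24. Quantile normalization moved the split of EtOH minus HF at 24 h from 135 higher and 601 lower to 243 and 450. Over the 500 genes with the largest HF response, the strength difference at 1 h was -0.029 in place of -0.076. In the same setting it was -0.251 at 6 h (exact permutation p = 0.0286, the smallest possible) in place of -0.088, at 24 h -0.92 in place of -0.297, and over all times -0.4 in place of -0.153. With all 72 arrays it was -0.028 at 6 h (exact permutation p = 0.543) and -0.191 at 24 h.

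Leaving out 1 animal at a time gave 1163 to 1373, 5032 to 5708 and 4240 to 4976 genes for the mean response at 1, 6 and 24 h, 4253 to 4567 for EtOH at 6 h, 3293 to 3751 for CHO at 6 h, 2860 to 3183 for HF at 24 h, and 1385 to 1781 and 1677 to 1965 for the baseline differences of EtOH from CHO and HF. Strength differences ran from -0.113 to -0.041, -0.134 to -0.056 and -0.34 to -0.248 at 1, 6 and 24 h, and from -0.169 to -0.137 over all times (exact permutation p 0.000571 to 0.00857).

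Other counts moved by over 1.5 times, where fewer samples are part of the change. For HF at 6 h and CHO at 24 h, leaving out 1 animal leaves 1 pair, assumed to vary like the other groups in every comparison that uses it. EtOH at 1 h ranged from 220 to 298 (223 and 220 without replicates 2 and 3) and at 24 h from 1114 to 1882 (1114 without replicate 1). CHO at 1 h ranged from 120 to 149 (149, 120 and 132 without replicates 1, 2 and 4) and at 24 h from 1405 to 1745 (1405 without replicate 4). HF at 1 h ranged from 95 to 261 (119 and 95 without replicates 1 and 2) and at 6 h was 1218 and 1702 without replicates 3 and 4. EtOH minus CHO ranged from 0 to 1 at 1 h (1 without CHO replicate 1), from 135 to 218 at 6 h (154 without EtOH replicate 2, 135 without CHO replicate 3) and from 225 to 650 at 24 h (277 without EtOH replicate 1, 225 without CHO replicate 2). EtOH minus HF ranged from 0 to 2 at 1 h (2 without HF replicate 4), from 63 to 289 at 6 h (166 without EtOH replicate 2, 63 and 73 without HF replicates 3 and 4) and from 405 to 1040 at 24 h (405 and 467 without EtOH replicates 1 and 3, 446 without HF replicate 4). HF minus CHO was 0 at 1 h in all limma fits, 0 to 1 at 6 h (1 without CHO replicate 2 or 3) and 0 to 6 at 24 h (2 and 6 without CHO replicates 2 and 4). At baseline HF minus CHO ranged from 6 to 24, with 11 and 13 without HF 1 h replicates 2 and 4, 15 without HF 6 h replicate 4, 11 without HF 24 h replicate 1, 6 without CHO 1 h replicate 2, 11 and 8 without CHO 6 h replicates 2 and 3, and 10 without CHO 24 h replicate 2. Arrays carry no counts, and their number limits what could be detected.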

Other observations

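The test in this part of differences present before PHx was chosen after the result was seen. Several gene groups not described so far differed before PHx or responded to it. Before PHx, CDK inhibitors and p53 targets were higher in EtOH than in CHO livers for 4 of 16 genes (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00411, and adjusted p = 0.213 with an estimated correlation), Phlda3, a p53 target, by log2 1.55. Interferon response genes were higher for 9 of 26 and lower for 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00411, and adjusted p = 0.541 with an estimated correlation). Glucocorticoid targets were lower for 3 of 14 and higher for 2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.00722, and adjusted p = 0.205 with an estimated correlation). Igfbp1 (1.67) was higher in EtOH than in CHO livers, and so were the inflammatory receptor Cd14 (1.51) and the bile acid exporter Abcc3 (1.60). Gclm, of glutathione synthesis, was lower, at -1.08. With the misplaced CHO columns kept as named, Igfbp1 (1.357) was no longer called and the glucocorticoid mean was -0.425 in place of -0.28. From the value table the interferon mean was 0.173 in place of 0.26. In 1 or more cohorts alone, which leaves fewer arrays, calls ended for Igfbp1 and Abcc3 and for the p53, interferon and glucocorticoid lists.

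After PHx, heat shock genes rose at 6 h for 8 of 15 and fell for 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0222, and adjusted p = 0.609 with an estimated correlation). NRF2 targets went both ways at 6 h, with 5 of 23 rising and 14 falling (5 and 14 adjusted over the list alone, camera adjusted p = 0.0161, and adjusted p = 0.476 with an estimated correlation), Hmox1 by 2.16 and Gclm at -2.09. ER stress genes rose at 24 h for 11 of 23 and fell for 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0028, and adjusted p = 0.325 with an estimated correlation), the chaperone partner Sdf2l1 by 1.69. Gluconeogenesis genes fell at 24 h for 10 of 18 and rose for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000505, and adjusted p = 0.0595 with an estimated correlation). Clock genes fell at 24 h in the mean of the diets for 9 of 17 and rose for 4 (10 and 4 adjusted over the list alone, camera adjusted p = 0.0201, and adjusted p = 0.19 with an estimated correlation). The fall lay in the control diets, with list means of -0.578 in CHO and -0.715 in HF livers against -0.036 in EtOH livers. Before PHx the clock list already stood lower in EtOH livers, by list means of -0.666 against CHO and -0.605 against HF. The list mean averages genes that move in opposite directions. In the 1 and 24 h cohorts, which are different animals, 710 genes were called in both, of which 142 rose in both, 294 fell in both and the others changed in opposite directions.

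A hypothesis is that part of the response differences between EtOH and the control diets reflects a difference already present before PHx that narrows after it. Of the 279 genes against CHO at 6 h, 89.2% had a baseline difference of the opposite sign in the control livers of the other cohorts (55.2% of all genes), and 136 lay closer to 0 after PHx. Of the 293 against HF, 84.6% had the opposite sign (57.4% of all genes) and 109 lay closer to 0. Narrowing may thus hold for part of these genes, and the values do not decide. At 24 h, 72.7% of the 440 genes against CHO (51% of all genes) and 77.3% of the 736 against HF (53.7% of all genes) had the opposite sign, but 67 and 156 lay closer to 0 after PHx. Closeness was judged from the baseline difference of the other cohorts plus the response difference. In the remaining genes the response difference had the same sign as the baseline difference or carried it past 0. The genes were chosen for a large response difference and the baseline came from other animals, so these counts do not decide on narrowing at 24 h either.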
